A study of Rattus norvegicus with 10 samples.

How the data were processed

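RNA was sequenced from 10 cultures of rat hippocampal neurons (Wistar strain, day 15 in vitro) in 5 groups of 2 biological repeats. Per the labels, the mock group received the mock solution of a chemical long-term potentiation (cLTP) protocol, and the other 4 groups were collected 5, 10, 60 and 120 min after the cLTP solution. The time at which the mock cultures were collected is not given in the sources used here. Per the labels' protocols, glial growth was suppressed on day 4 with a fluorodeoxyuridine and uridine mixture. The same protocols state that ribosomal RNA was depleted and poly(A) RNA was selected in 3 rounds on oligo(dT) beads.

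Per the submitters' processing notes, the tools were bcl2fastq, TopHat2 2.1.0, HTSeq and edgeR, on the rat genome build rn6; the annotation and the strand setting of the counting are not given in the sources used here. The authors deposited a table of 11615 genes that, per the file headers, gives CPM (reads scaled to a common library total) for each library, with chromosome, start, end, strand and a length per gene. For each of the 4 times against mock, the deposited table also holds the authors' log2 fold change, p-value and adjusted p-value. The 2 mock columns were repeated with identical values beside each time, so that 6 of the 16 per-library columns were copies and were not used. In 22 rows a spreadsheet serial number stands in place of the gene symbol; these rows were tested and counted but left unnamed.

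Within each library every CPM value lay within 0.01 reads of a whole multiple of a single step, as whole reads divided by a library total would. This step put the totals at 32961534 reads for 5 min replicate 1 and 54040657 reads for 10 min replicate 1, with the other libraries between 36585716 and 42933638 reads. The lowest value listed in any library was worth 9 to 20 reads, so rarer transcripts were not analysed here. The design had been written for read counts with a negative binomial test; since the table holds CPM, its written fallback was used and no count model was run.

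CPM values were divided by trimmed-mean (TMM) factors, computed with 30% of log ratios and 5% of mean levels trimmed, and transformed as log2(CPM + 1). A fold change is on this scale, which understates the change of low genes. The 10 libraries were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group, an intensity trend in the variance prior and 5 residual degrees of freedom. Each time was compared with mock, neighbouring times were compared with each other, and the 4 times were tested together for a change at any time. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 11615 genes. All p-values of single genes in the text are from these two-sided limma tests, and values are TMM-scaled CPM with the SD of 2 libraries. Since the labels call the samples biological repeats, p-values measure the spread between separate cultures as far as these labels go. Figures were drawn with matplotlib 3.10.9.

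Before the data were examined, 20 gene lists were fixed with 508 members, of which 473 were matched in the table by symbol or by a synonym from the RefSeq gene table of assembly GRCr8. They cover immediate-early transcription factors, activity-regulated effectors, feedback regulators, glutamate receptors, postsynaptic scaffolds, presynaptic release, GABAergic genes, potassium and HCN channels, heat shock, the ATF4 and unfolded protein response, cholesterol synthesis, inflammatory and NF-kB targets, oxidative phosphorylation, ribosomal proteins, and markers of astrocytes, microglia, oligodendrocytes, vascular cells and fibroblasts, cycling cells and excitatory neurons. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, each adjusted over the 80 combinations of list and time. Camera compares a list with all other genes; fry tests whether the members of a list move, on balance, to one side.

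The rule for named genes was also fixed before the data were examined. It takes, for each time, the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1 and both cLTP libraries on the same side of both mock libraries. It adds up to 4 called members of each list by p, or up to 2 where none was called, and at every time Fos, Arc, Egr1, Npas4, Nr4a1, Bdnf, Homer1 and Nptx2. For each comparison of neighbouring times it takes the 4 largest rises and falls. Genes named outside the rule are said to be chosen after their values were seen. Values of some genes the rule takes are not reported here.

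Alternatives covered other scaling factors, limma-voom on the read-scale values, filters, the pseudocount, stricter thresholds, fits of only the groups compared, a block for the repeat number, and each library left out in turn. After the data were examined, a fit without the 5 min libraries and a fit with sample weights were added. Overlaps between times were set beside 100 simulated sets of unchanged groups that share the mock libraries. With 2 mock libraries the controls could not be split into parts of at least 2. No group has 3 or more libraries, so other splits of the samples were not counted.

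The steps were tested on simulated data: counts drawn for the 11615 genes from the measured means and library totals with a dispersion of 0.005, with 200 genes changed. For 60 min against mock, 46 of 50 genes changed by 1.5-fold were recovered, and 16 of 50 at the smallest fold simulated, which lay below 1.5. In the simulation of 5 min against mock the numbers were 45 of 50 and 8 of 50. False calls made up 8% of the calls in the simulation of 60 min, 6.7% for 10 min, 3.7% for 120 min and 3.2% for 5 min.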

Results

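Messenger RNA levels were measured by RNA sequencing in cultured hippocampal neurons of the rat at 5, 10, 60 and 120 min after a cLTP stimulus, a chemical treatment used to potentiate synapses across a whole dish, and in mock-treated cultures. Each of the 5 groups had 2 biological repeats. Between 32961534 and 54040657 reads stood behind each of the 10 libraries, and 11615 genes were tested. Transcripts known from several cell types were measured in the mock group. The dendritic protein gene Map2 was at 880 ± 57 CPM (SD, n = 2) and the intermediate filament gene Vim, abundant in astrocytes and fibroblasts, at 5100 ± 130 CPM. The fibroblast collagen gene Col1a1 was at 1110 ± 63 CPM and the microglial complement gene C1qa at 58.2 ± 1.2 CPM.

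The libraries of 60 min and 120 min stood apart from all others, and those of 120 min lay farthest from mock. The first principal component held 56.5% of the variance and ran from the mock, 5 min and 10 min libraries (-14.43 to -9.95) through 60 min (8.15 and 8.42) to 120 min (25.73 and 26.25). The second, with 21.6%, separated the 60 min libraries at -17.96 and -17.91 from all others. Within the 5 min group, replicate 2 stood at -15.56 on the third component (9.5% of variance) while replicate 1 stood at -2.12. The SD of the log2 difference between replicates was 0.164 in the 5 min pair and 0.113 to 0.125 in the other 4 pairs.

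**Figure D1:**
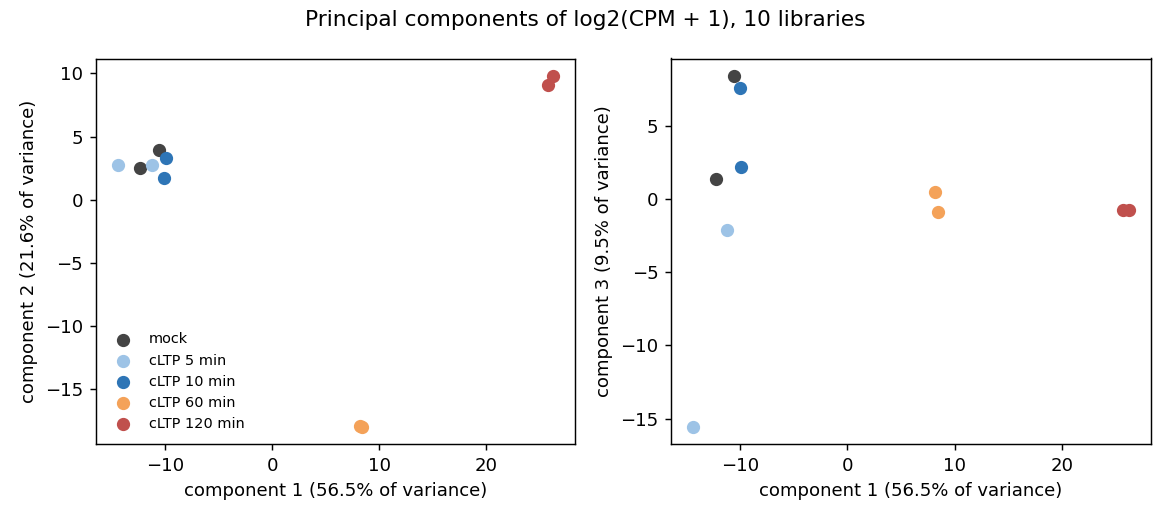
Positions of the 10 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(CPM + 1), each point a library, axes in component units with the share of variance. The 120 min libraries lie at 25.73 and 26.25 on component 1, and the second 5 min library lies at -15.56 on component 3.

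**Figure D2:**
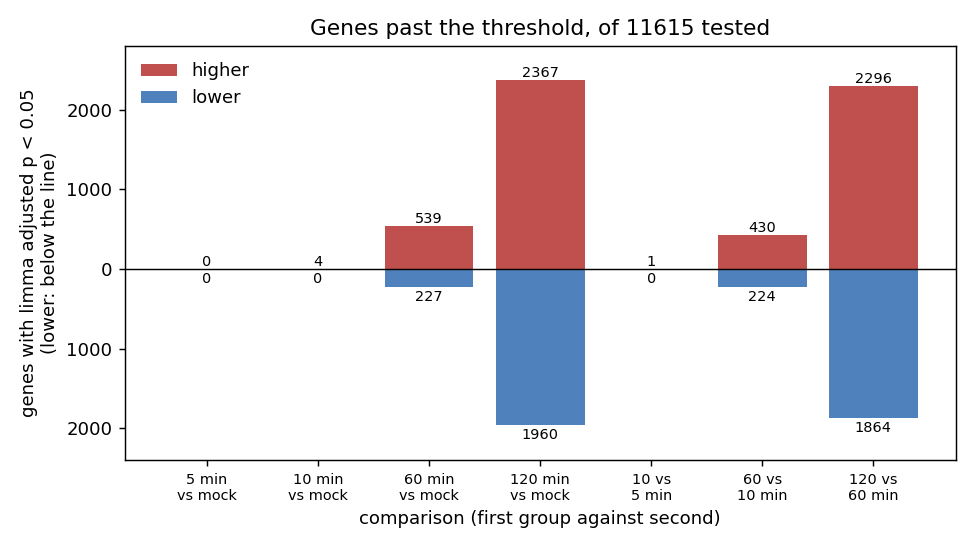
Number of genes past limma's adjusted p threshold of 0.05 in each comparison, bars above the line for genes higher and below the line for genes lower in the first group named. Calls number 0 at 5 min, 4 at 10 min, 766 at 60 min and 4327 at 120 min against mock.

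The comparison of 5 min with mock asked which transcripts had already moved within minutes. No gene passed the threshold with limma (0 higher, 0 lower, smallest adjusted p = 0.19), while 1862 genes had an unadjusted p under 0.05; limma-voom also called 0. Arc, an activity-induced cytoskeletal protein at synapses, was at 33.1 ± 0.47 CPM against 29 ± 2 CPM in mock (log2 fold change 0.19, SE 0.06, adjusted p = 0.22). Junb, an AP-1 transcription factor, was at 83.6 ± 7.7 CPM against 73.2 ± 1.9 CPM (adjusted p = 0.21), and the orphan nuclear receptor gene Nr4a2 at 30.1 ± 0.44 CPM against 25.4 ± 1.3 CPM (adjusted p = 0.19). Fos (84.3 ± 20 against 96.2 ± 16 CPM), Egr1 (31.1 ± 1.1 against 32 ± 2.5 CPM), Npas4 (7.75 ± 1.9 against 7.94 ± 0.61 CPM) and Nr4a1 (14.7 ± 1.7 against 16.7 ± 2.4 CPM) did not pass (adjusted p from 0.49 to 0.87). Bdnf was at 133 ± 2.7 CPM against 113 ± 8.3 CPM (adjusted p = 0.28).

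Among the gene lists at 5 min, camera with its preset correlation put ribosomal proteins (44 measured, median log2 fold change 0.14, adjusted p = 4.6e-15), oxidative phosphorylation subunits (39 measured, 0.11, adjusted p = 7.1e-12) and ATF4 and unfolded protein response genes (23 measured, 0.04, adjusted p = 0.0075) above other genes. It put microglia and macrophage markers (15 measured, -0.14, adjusted p = 0.003) below them. None of these 4 held with an estimated correlation, where the adjusted p was 0.41 for ribosomal proteins, 0.41 for oxidative phosphorylation, 0.38 for the ATF4 list and 0.43 for microglia. The 5 min calls rested on which library was used. With only replicate 2 for that time 110 genes were higher and 588 lower, with only replicate 1 the counts were 0 and 0, and without mock replicate 2 the lower count was 1. The authors' deposited table holds 98 genes past its adjusted p of 0.05 at 5 min, 4 higher and 94 lower.

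At 10 min the first immediate-early genes were above mock. Ier2, an immediate-early response factor, rose 1.67-fold (33.1 ± 1.2 against 19.4 ± 0.16 CPM, log2 fold change 0.74, SE 0.09, adjusted p = 0.019) and Junb rose 1.63-fold (120 ± 2.3 against 73.2 ± 1.9 CPM, adjusted p = 0.0012). Jun, another AP-1 subunit, and Arc each rose 1.36-fold (211 ± 12 against 154 ± 5.4 CPM and 39.9 ± 2.7 against 29 ± 2 CPM, adjusted p = 0.048 for each). These 4 genes were all that passed, with 0 lower in limma and 0 lower in limma-voom; 1148 genes had an unadjusted p under 0.05. The authors' deposited table, from the same libraries, holds 132 genes past its adjusted p of 0.05 at 10 min, 67 higher and 65 lower. All 4 limma calls were among them in the same direction. In the fit without a block for the repeat number, Junb was also the only gene called between 10 and 5 min (log2 difference 0.52, SE 0.06, adjusted p = 0.028).

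Other members of the early response at 10 min lay above mock without passing over all genes. Fos was at 142 ± 24 CPM against 96.2 ± 16 CPM (adjusted p = 0.3) and Nr4a1 at 23.1 ± 3 against 16.7 ± 2.4 CPM (adjusted p = 0.3). Egr1 was at 38.6 ± 3.6 against 32 ± 2.5 CPM (adjusted p = 0.31), Npas4 at 9.86 ± 0.83 against 7.94 ± 0.61 CPM (adjusted p = 0.52), and Socs3, a brake on cytokine receptors, at 18.2 ± 2.3 against 10.7 ± 1.5 CPM (adjusted p = 0.11). Adjusted over the list alone, 13 of 25 immediate-early transcription factors were higher and 2 lower, against 3 higher over all genes. The list as a whole had a median log2 fold change of 0.19 (camera adjusted p = 1.4e-08, fry adjusted p = 0.037; adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, 8 of 27 feedback regulators were higher and 2 lower, and 9 of 15 microglia and macrophage markers were lower, among them C1qb at 45.2 ± 1.9 against 56.1 ± 0.57 CPM (adjusted p = 0.15 over all genes). The microglia list had a median of -0.24 (camera adjusted p = 8.4e-10, fry adjusted p = 0.041; adjusted p = 0.25 with an estimated correlation). Another 11 lists passed camera with medians from -0.15 to 0.09. Their adjusted p was 0.38 to 0.81 with an estimated correlation, and fry called none of them (adjusted p from 0.12 to 0.7).

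The 10 min calls were fragile. Jun and Arc missed the threshold with limma-voom, and the count of higher genes was 0 without 10 min replicate 2, 9 without either 5 min library and 1 without any other single library. The lower count was 3 without either 5 min library and 1 without mock replicate 1 or 10 min replicate 1. Between 5 and 10 min 740 genes differed without 5 min replicate 1. Without the 5 min libraries, a choice made after the data were examined, 9 genes were higher and 3 lower. The genes added on the higher side, also named after their values were seen, were Gadd45g, Socs3, Ier3, Ppp1r15a and Ptrf, and the 3 lower were Bgn, Bc1 and Plagl1.

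By 60 min the immediate-early genes stood far above mock. All 25 measured immediate-early transcription factors rose (median log2 fold change 2.18, camera adjusted p = 3.5e-74, and adjusted p = 0.01 with an estimated correlation). Atf3, a stress-induced bZIP factor, rose 24.3-fold to 433 ± 4.9 CPM (log2 fold change 4.6, SE 0.05, adjusted p = 1.2e-13), Fosb 16.4-fold, Maff 13.4-fold, Nr4a1 11.2-fold to 196 ± 14 CPM and Csrnp1 10.8-fold. Fos (chromosome 6, 109300433 to 109303299, rn6) rose 6.63-fold to 640 ± 27 CPM from 96.2 ± 16 CPM (log2 fold change 2.73, SE 0.15, adjusted p = 8.6e-08), Egr1 5.81-fold to 190 ± 14 CPM and the neuronal activity factor Npas4 5.39-fold to 47.2 ± 2.6 CPM. In total 539 genes were higher and 227 lower than in mock, 6.6% of those tested, and 126 rose at least 2-fold while 0 fell that far. The authors' deposited table holds 1072 genes past its adjusted p of 0.05 at 60 min. Of the 766 limma calls, 764 were among them in the same direction.

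The steepest rise at 60 min was that of Nrarp, a feedback inhibitor of Notch signalling (chromosome 3, 2396143 to 2398691, rn6), which went from 1.03 ± 0.13 to 71.5 ± 0.74 CPM, 35.7-fold on the log2(CPM + 1) scale (SE 0.11 log2, adjusted p = 2.9e-11). Other large rises were those of Tfpi2, a secreted protease inhibitor (17.6-fold), Gem, a small GTPase that restrains calcium channels (17.5-fold), Adamts1, a secreted metalloprotease (15.2-fold), Angptl4 (12.6-fold), Socs3 (12.1-fold) and the chemokine Cxcl1 (10.7-fold, 152 ± 10 against 13.3 ± 2.7 CPM).

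Of 29 measured activity-regulated effectors, 14 were higher at 60 min and 0 lower (camera adjusted p = 5.4e-17; adjusted p = 0.072 with an estimated correlation), and 18 were higher when adjusted over the list alone. Gadd45g and Gadd45b, stress-inducible regulators of DNA demethylation and growth, rose 9.61-fold and 5.83-fold, the clock gene Per1 2.7-fold and Arc 2.61-fold to 77.3 ± 4 CPM. Other effectors had not passed at this time: Bdnf was at 125 ± 4.9 CPM (adjusted p = 0.52), Homer1 at 89.4 ± 7.9 CPM (adjusted p = 0.51) and Nptx2 at 38.1 ± 4.4 CPM (adjusted p = 0.17). Feedback regulators rose alongside, 21 of 27 members (median 1.03, camera adjusted p = 8.1e-36, and adjusted p = 0.0071 with an estimated correlation). Adjusted over the list alone, 23 were higher and 1 lower. Among those that rose were Trib1 (6.61-fold), the NF-kB inhibitor Nfkbia (4.68-fold to 569 ± 19 CPM) and the phosphodiesterase Pde4b (4.09-fold).

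Inflammatory and NF-kB targets rose with them at 60 min, 12 of 16 measured members, while Il1b, named after its value was seen, was lower (median 1.39, camera adjusted p = 1.2e-28, and adjusted p = 0.021 with an estimated correlation), and 14 were higher and 1 lower when adjusted over the list alone. Irf1 rose 8.42-fold to 350 ± 11 CPM, the apoptosis inhibitor Birc3 7.24-fold, the cytokine gene Lif 6.68-fold and the adhesion molecule Icam1 3.07-fold. Of the ATF4 and unfolded protein response list, 7 of 23 members were higher, and 9 when adjusted over the list alone (camera adjusted p = 4.3e-06; adjusted p = 0.18 with an estimated correlation), led by the phosphatase subunit Ppp1r15a (5.62-fold) and Cebpb (4.63-fold), while Atf4 itself rose 1.27-fold. Among 20 heat shock genes 6 were higher and 1 lower (camera adjusted p = 0.001; adjusted p = 0.26 with an estimated correlation), with Hspa1b at 1.67-fold. Among 24 cholesterol genes 4 were higher (adjusted p = 0.015; adjusted p = 0.55 with an estimated correlation), among them Insig1 (1.67-fold) and Idi1 (1.23-fold).

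Falls at 60 min were small. The largest were those of Zic5 (6.5 ± 0.4 against 12.7 ± 0.18 CPM, log2 fold change -0.87, SE 0.1, adjusted p = 0.00016), Zfp112 (-0.86), the Krüppel-like factor gene Klf15 (21.7 ± 0.023 against 39.7 ± 0.77 CPM, -0.84, adjusted p = 6.6e-07) and Txnip, an inhibitor of glucose uptake (188 ± 1.8 against 332 ± 13 CPM, -0.82). Zfp111, Zfp641, the retinoic acid receptor gene Rarg and Axin2, a feedback inhibitor of Wnt signalling, fell by 0.72 to 0.76 on the log2 scale.

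Genes of the synapse showed few calls at 60 min. In limma, 0 of 28 glutamate receptor genes and 0 of 27 presynaptic genes passed. Higher were 1 of 30 postsynaptic genes (LRRTM1), 2 of 27 GABAergic genes (Slc32a1 and Cck), 1 of 28 potassium and HCN channel genes (Kcnj2, an inward rectifier, 2-fold) and 1 of 19 excitatory neuron markers (Neurod2). Camera put none of these 6 lists apart from other genes (adjusted p from 0.076 to 0.82). Oxidative phosphorylation and ribosomal protein genes had 0 calls of 39 and 0 of 44, and cell cycle markers 0 of 15. Among markers of other cells, Olig2 and Olig1 were higher (2-fold and 1.19-fold, of 13 oligodendrocyte markers), Atp1b2 was lower among 15 astrocyte markers, C1qb among 15 microglia markers, and Col1a1 and Pdgfrb among 9 vascular and fibroblast markers. The microglia and vascular lists lay below other genes by camera (medians -0.15 and -0.13, adjusted p = 0.00032 and 0.013; adjusted p = 0.41 and 0.43 with an estimated correlation).

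With library totals in place of TMM factors the 60 min calls split into 447 higher and 333 lower (57.3% higher), and leaving out 60 min replicate 1 left 341 higher and 94 lower. The lower count was 89 without mock replicate 1 and 128 without 60 min replicate 2. Of the small changes named, those of LRRTM1, Slc32a1, Cck, Neurod2, C1qb, Olig1 and Pdgfrb each lost the call in at least 2 of the 10 refits that leave out a library, and LRRTM1, Cck and Neurod2 also with library totals.

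**Figure D3:**
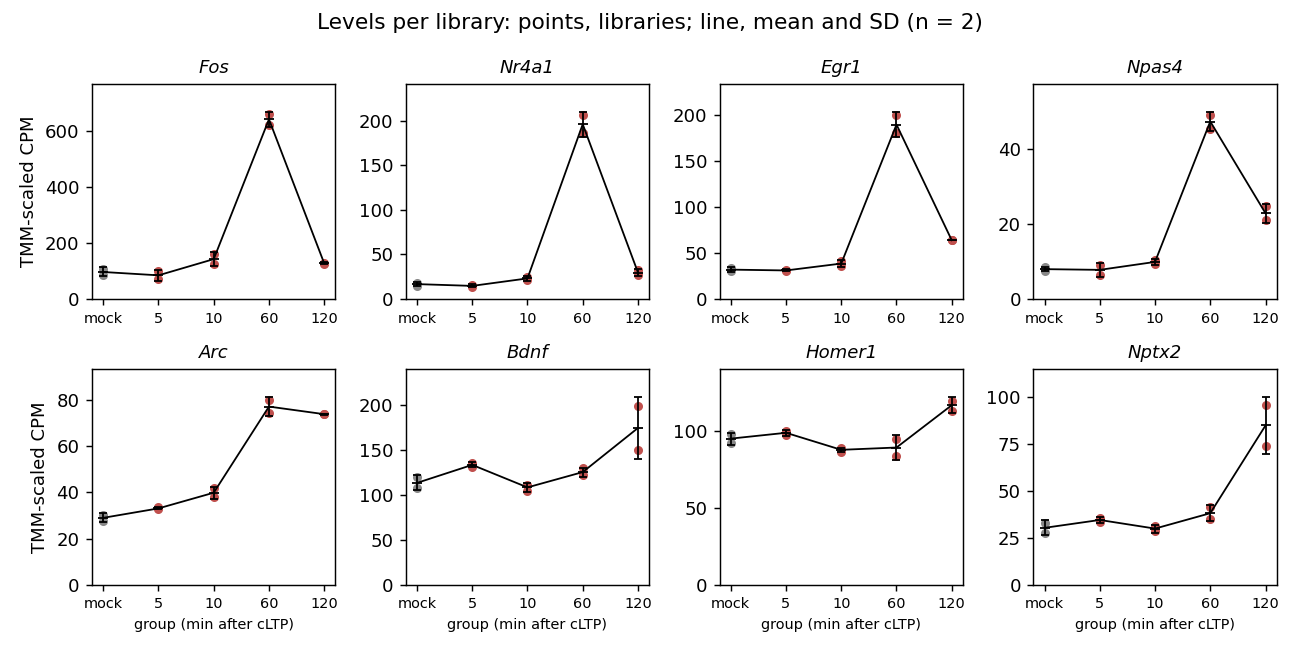
TMM-scaled CPM of 8 genes fixed before the data were examined, by group (mock and minutes after cLTP); points are libraries, the black line joins means and bars are the SD of 2 libraries. Fos, Nr4a1, Egr1 and Npas4 are highest at 60 min (640, 196, 190 and 47.2 CPM), whereas Nptx2 and Bdnf are highest at 120 min (84.9 and 174 CPM).

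At 120 min 2367 genes were higher than in mock and 1960 lower (37.3% of those tested), 244 of them at least 2-fold higher and 6 at least 2-fold lower. Tfpi2 reached 88.9 ± 1.9 CPM from 0.792 ± 0.36 CPM (50.7-fold on the log2(CPM + 1) scale, SE 0.15 log2, adjusted p = 8e-11). Thbs1, an astrocyte-secreted protein that promotes synapse formation, rose 21.9-fold to 552 ± 92 CPM and the pattern-recognition protein gene Ptx3 21.8-fold to 303 ± 11 CPM. Further rises were those of the AP-1 gene Fosl1 (17.6-fold), the cytokine gene Clcf1 (16.6-fold), Angptl4 (15.2-fold), the chemokine Cxcl10 (13.4-fold) and the growth factor Hbegf (12.5-fold).

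Of the 29 activity-regulated effectors 24 were higher and 0 lower at 120 min (median 0.61, camera adjusted p = 3.8e-11; adjusted p = 0.13 with an estimated correlation). Adjusted over the list alone, 25 were higher. Tested directly from 60 to 120 min, 11 were higher and 5 lower, and the list did not pass (median 0.13, camera adjusted p = 0.4; adjusted p = 0.75 with an estimated correlation). Nptx2, a pentraxin that clusters AMPA receptors, rose 2.73-fold to 84.9 ± 15 CPM (adjusted p = 2.2e-06), Plk2 2.64-fold and Arc 2.5-fold to 74 ± 0.26 CPM. Smaller rises were those of Vgf (1.68-fold), the neurotrophin gene Bdnf 1.52-fold to 174 ± 34 CPM (adjusted p = 0.00059) and Homer1 1.22-fold to 117 ± 5.1 CPM (adjusted p = 0.0028). Immediate-early transcription factors remained above mock in all 25 cases (median 1.28, camera adjusted p = 2.6e-23; adjusted p = 0.072 with an estimated correlation), with Fos at 127 ± 3.1 CPM (1.32-fold, adjusted p = 0.0495), Egr1 at 64 ± 0.2 CPM (1.97-fold) and Npas4 at 22.8 ± 2.5 CPM (2.66-fold). The call of Fos at 120 min was lost with library totals, with a pseudocount of 0.1, and without mock replicate 2 or any single 60 or 120 min library (adjusted p from 0.0056 to 0.33 over all alternatives). Of the 27 feedback regulators 19 were higher and 4 lower, and 19 and 5 when adjusted over the list alone (adjusted p = 1.6e-06; adjusted p = 0.072 with an estimated correlation), with Rcan1, an inhibitor of calcineurin, at 2.75-fold and the MAP kinase phosphatase gene Dusp5 at 3.38-fold. The 4 lower, named after their values were seen, were Spry1, Btg2, Nfkbia and Pde10a.

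Inflammatory and NF-kB targets were higher in 14 of 16 cases at 120 min (median 1.23, camera adjusted p = 8.2e-12; adjusted p = 0.072 with an estimated correlation). The chemokine Ccl2 rose 9.02-fold to 480 ± 28 CPM, Lif 6.55-fold and the NF-kB subunit gene Nfkb1 5.32-fold to 314 ± 16 CPM. Cholesterol genes were higher in 13 of 24 cases and lower in 2 (median 0.19, adjusted p = 0.00055; adjusted p = 0.43 with an estimated correlation), with Msmo1, a sterol synthesis enzyme, at 2.17-fold and Insig1 at 1.93-fold. Of 23 ATF4 and unfolded protein response genes 14 were higher and 1 lower, or 3 lower with library totals (adjusted p = 0.00031; adjusted p = 0.27 with an estimated correlation), and of 20 heat shock genes 8 were higher and 2 lower (adjusted p = 0.0056; adjusted p = 0.34 with an estimated correlation), led by the small heat shock protein gene Hspb8 (2.75-fold) and its partner Bag3 (2.27-fold).

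Synaptic and neuronal lists fell at 120 min by both camera and fry. Called members were 21 lower of 27 presynaptic genes, 20 lower and 3 higher of 30 postsynaptic genes, and 17 lower of 27 GABAergic genes. They were 16 lower of 28 glutamate receptor genes, 16 lower of 28 potassium and HCN channel genes, and 10 lower and 1 higher of 19 excitatory neuron markers. Their median log2 fold changes ran from -0.27 to -0.22, with camera adjusted p from 2.5e-07 to 0.00033 and fry adjusted p from 0.0033 to 0.036. Adjusted over the list alone, 22 presynaptic, 21 GABAergic and 11 excitatory genes were lower, and the other 3 counts did not move. No call held with an estimated correlation, where the adjusted p was 0.41 for presynaptic genes, 0.44 for postsynaptic genes, 0.34 for GABAergic genes and 0.38 for each of the other 3 lists. Examples are the AMPA receptor gene Gria2 (854 ± 9 against 989 ± 17 CPM, log2 fold change -0.21, SE 0.04, adjusted p = 0.0022) and the NMDA receptor gene Grin1 (253 ± 4.3 against 297 ± 4.3 CPM). Others are the scaffold gene Shank1 (72.2 ± 1.4 against 102 ± 1.3 CPM, -0.49), synapsin Syn1 (-0.32) and the GABA receptor gene Gabbr2 (185 ± 0.99 against 239 ± 6.9 CPM, -0.37). Among excitatory markers the bHLH factors Neurod6 (-0.61, adjusted p = 7.5e-07) and Bhlhe22 (-0.5) fell. The postsynaptic members that rose were Baiap2 (1.36-fold), Dlg1 and Synpo, the last 2 named after their values were seen.

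Markers of other cell types moved at the same time. Microglia and macrophage markers were lower in 11 of 15 cases (median -0.37, camera adjusted p = 3e-05, fry adjusted p = 0.0064; adjusted p = 0.38 with an estimated correlation), for example C1qa at 40.2 ± 0.18 CPM (log2 fold change -0.52) and Ctss (-0.55). Oligodendrocyte markers were lower in 3 of 13 (Olig1, Mobp and Mog; median -0.14, adjusted p = 0.016; adjusted p = 0.43 with an estimated correlation) and in 8 with library totals (median -0.21). Astrocyte markers split into 5 higher, among them Vim (6860 ± 11 CPM, 1.34-fold) and Sox9 (1.35-fold), and 1 lower, Atp1b2, of 15; with library totals 3 were higher and 3 lower, and the median of 0.05 became -0.01. Vascular and fibroblast markers had 2 higher (Flt1, Tagln) and 2 lower (Pdgfrb, Col1a1) of 9, and of 15 cell cycle markers only Mki67 was lower. Ribosomal protein genes were higher in 6 of 44 cases (median 0.1, adjusted p = 0.003; adjusted p = 0.75 with an estimated correlation) and in 0 with library totals, and oxidative phosphorylation genes were lower in 3 of 39 (Ndufs1, Ndufa4, Ndufa8; median -0.04) and in 12 with library totals (median -0.1). Adjusted over the list alone, 0 genes of either list passed in limma.

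Further large falls at 120 min were those of Klf15 (13.5 ± 0.31 against 39.7 ± 0.77 CPM, log2 fold change -1.49, SE 0.06, adjusted p = 1.8e-09), G0s2, an inhibitor of lipolysis (-1.38), Stard8 (-1.33), the bHLH gene Atoh8 (-1.03), Apobec1 (-1.02) and the homeobox gene Meis1 (-0.96). With library totals in place of TMM factors the calls split into 1786 higher and 3123 lower (36.4% higher), against 2367 and 1960 with TMM factors. The lower count was 1121 without mock replicate 2, 1245 without 120 min replicate 1 and 1106 without 120 min replicate 2. Rpl5, Rpl7, Rpl10, Rpl4, Ndufs1, Ndufa4, Ndufa8, Mobp, Mog and Mki67 each lost the call in at least 1 of these refits.

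**Figure D4:**
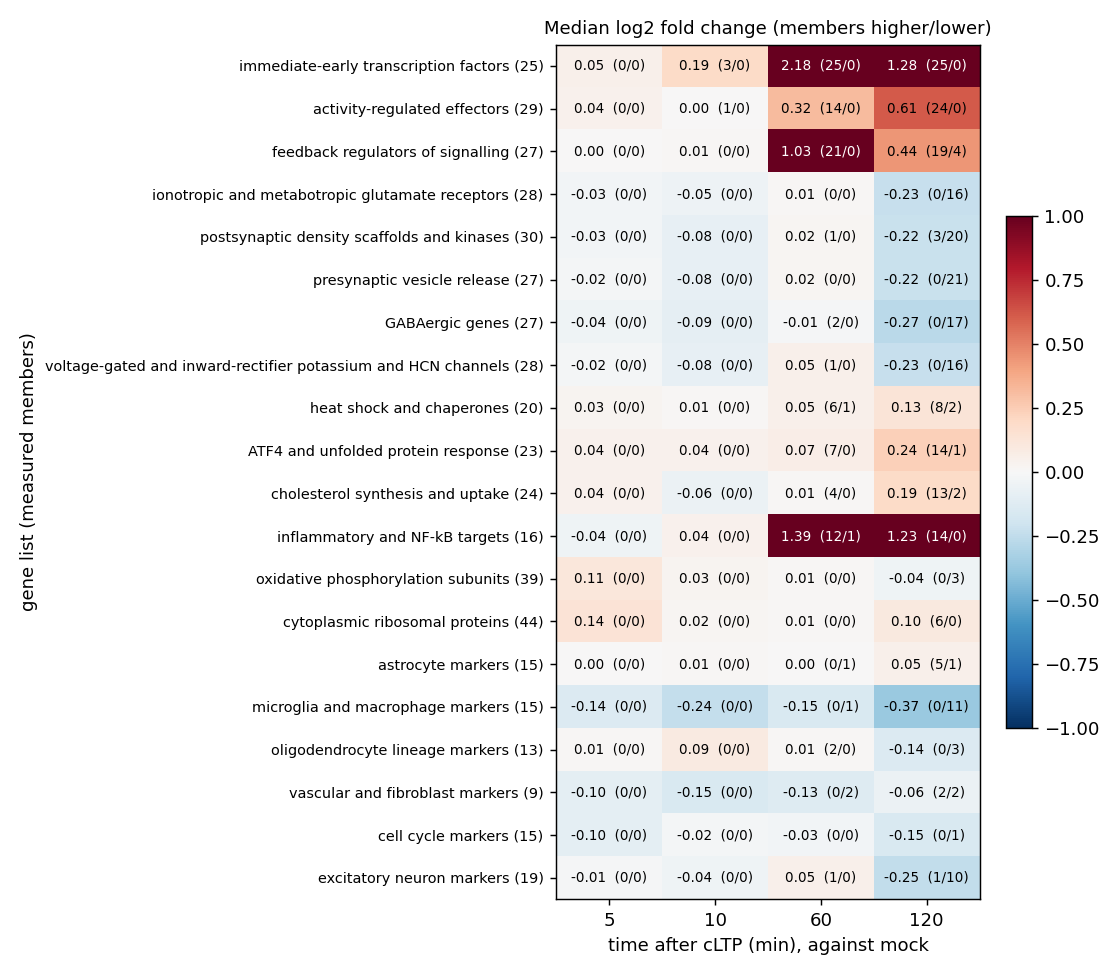
Median log2 fold change against mock of the 20 gene lists (rows, with the number of measured members) at each time after cLTP (columns, min), with the members higher and lower past the threshold in parentheses. Immediate-early transcription factors reach 2.18 at 60 min and 1.28 at 120 min, and the microglia list reaches -0.37 at 120 min.

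Between neighbouring times, 654 genes differed from 10 to 60 min (430 higher, 224 lower) and 4160 from 60 to 120 min (2296 higher, 1864 lower). From 60 to 120 min the immediate-early list turned over: 16 of its 25 members fell and 6 rose further (camera adjusted p = 9.8e-06; adjusted p = 0.35 with an estimated correlation). Nr4a1 fell by 2.68 on the log2 scale to 29.7 ± 3.6 CPM, Fos fell by 2.33, Egr1 fell by 1.56 and Npas4 fell by 1.02, while the change of Arc (-0.06, SE 0.06, adjusted p = 0.48) did not pass. The largest falls of this interval were those of Nfkbiz (108 ± 11 to 11.9 ± 0.87 CPM), Btg2 (329 ± 40 to 45.4 ± 0.64 CPM) and Irf1 (350 ± 11 to 50.6 ± 7.3 CPM). The largest rises were those of Clcf1 (4.34 ± 0.084 to 59 ± 2.7 CPM, 11.2-fold), Nfkb1 (5.1-fold), the fibronectin receptor gene Itga5 (4.63-fold) and the interferon-induced GTPase gene Gbp2 (255 ± 1.9 to 1180 ± 23 CPM, 4.63-fold). Bdnf, Homer1 and Nptx2 rose in this interval by 0.46, 0.38 and 1.13 on the log2 scale (adjusted p = 0.0039, 5e-04 and 2.5e-05). The 6 synaptic and neuronal lists also fell in this interval tested directly, with medians from -0.28 to -0.22 (fry adjusted p from 0.0019 to 0.014; camera adjusted p from 0.35 to 0.48 with an estimated correlation). Counts were 398 from 10 to 60 min without 60 min replicate 1, 412 without 60 min replicate 2 and 417 without 10 min replicate 2, and 2692 from 60 to 120 min without 120 min replicate 2.

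Any change over the course was found for 4802 genes. For 3604 of them (75.1%) the largest change against mock was at 120 min. The numbers were 592 at 60 min, 139 at 10 min and 467 at 5 min. Of these 467, 365 had a fall there, although no gene passed the threshold at 5 min against mock. The time of the largest change is a description without a test of its own. Without 120 min replicate 1 or 2 the number with any change was 2706 or 2489. Of the 539 genes higher at 60 min, 420 were also higher at 120 min, where independent lists of these sizes would share 109.8. Of the 227 genes lower at 60 min, 85 were also lower at 120 min, against 38.3. Simulated unchanged groups sharing the mock libraries shared at most 1 gene in either direction; with no effects they hold few calls, so this does not measure what the shared libraries add to lists of these sizes. The log2 fold changes of 60 and 120 min had a correlation across genes of 0.57, against 0.5 in the simulation, and a covariance of 0.0565 against 0.0034; part of any excess may come from the shared mock libraries, which could not be split. Tested directly, 179 of the 539 genes fell between 60 and 120 min, 218 rose further and 142 showed no call. Of the 227 lower genes 133 rose back and 10 fell further.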

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

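The tests of library depth, of the share of neuronal RNA and of microglial RNA were chosen after the results were seen. So were the leave-one-out counts read for the 5 min group and the tests without mock libraries, with their split by time. The other tests in this part were written down beforehand. Each result in the next 2 paragraphs stands here because time points differed by a direct test.

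Between neighbouring times, 1 gene differed from 5 to 10 min (Junb, log2 difference 0.52), 654 from 10 to 60 min and 4160 from 60 to 120 min. The counts here are from the fit without a block for the repeat number. From 10 to 60 min the differences were 4.85 for Nrarp, 4.41 for Atf3, 4.15 for Fosb, 4 for Gem, 3.04 for Nr4a1, 2.27 for Egr1, 2.17 for Fos, 2.15 for Npas4 and 0.94 for Arc on the log2 scale. In the same interval Zc2hc1c changed by -0.94, Klf15 by -0.88, the interferon-induced chaperone gene Rtp4 by -0.87 and Zfp112 by -0.84. From 60 to 120 min Clcf1 changed by 3.49, Nfkb1 by 2.35, Itga5 by 2.21, Gbp2 by 2.21, Nptx2 by 1.13, Bdnf by 0.46 and Homer1 by 0.38, and falls were -3.08 for Nfkbiz, -2.82 for Btg2, -2.77 for Irf1, -2.68 for Nr4a1, -2.33 for Fos, -1.56 for Egr1 and -1.02 for Npas4. Rtp4 lost its call with limma-voom and in 5 of the 10 refits that leave out a library, and Junb lost its call from 5 to 10 min in 7 of these refits. The count from 5 to 10 min was 740 without 5 min replicate 1, 2 without either mock replicate and 0 without any other single library. From 10 to 60 min it was 398 and 412 without 60 min replicate 1 and 2 and 417 without 10 min replicate 2, and from 60 to 120 min 2692 without 120 min replicate 2.

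A set of 22 genes was higher than mock at 60 min and lower than mock at 120 min, and 48 genes went the other way. Among the 22, chosen for naming after their values were seen, were Nfkbiz (2.38 at 60 min, -0.71 at 120 min) and the NF-kB inhibitor gene Nfkbia (2.23 and -0.39). Others of the 22, chosen in the same way, were the antiproliferative gene Btg2 (2.52 and -0.3), Ppp1r3c (0.77 and -0.69) and Id2 (0.42 and -0.71). Among the 48 were Zic5 (-0.87 and 0.37) and Piezo1, a mechanosensitive channel (-0.25 and 1.08). Others of the 48 were Kctd11 (-0.45 and 0.78) and Map3k1 (-0.42 and 0.79). Piezo1, Kctd11 and Map3k1 were chosen for naming after their values were seen.

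The 5 min group gave no call with both libraries, while the authors' deposited table holds 94 genes lower at that time. One library is a candidate source of these falls: with replicate 2 alone standing for 5 min, limma called 588 genes lower, and with replicate 1 alone it called 0. Whether the authors' 94 genes are among those called with replicate 2 alone was not checked. A bias by gene length was not particular to the 5 min pair, whose difference followed listed gene length with a Spearman's rho across genes of -0.16. The rho was -0.29 in the 10 min pair, 0.25 in the 60 min pair, -0.03 in the mock pair and 0 in the 120 min pair. A contribution of length to the falls at 5 min cannot be excluded by these values. Library depth stays open: the 10 min pair, which holds the deepest library, had a replicate SD of 0.124 against 0.164, but single pairs of cultures differ for other reasons too. Whether replicate 2 was collected, handled or responding differently stays open, and as a biological repeat it may hold a real difference between cultures.

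The fall of neuronal gene lists at 120 min covered 159 genes with a median log2 fold change of -0.23, of which 100 were called lower and 4 higher, and no list call held with an estimated correlation (adjusted p from 0.34 to 0.44). A lower share of neurons in the RNA stays open. Microglia markers had a median of -0.37 (SD 0.15 over 15 members, all below 0) while astrocyte markers had 0.05 (SD 0.23). The shares of neurons and microglia could fall together, so these marker lists cannot decide it. Neuronal genes are long (median span 63.2 kb), yet random gene sets matched on genomic span had medians from -0.08 to 0. Time in the dish cannot be told apart from the stimulus, since 0 of the 4 cLTP times have a mock group labelled with that time, and when the mock cultures were collected is not given in the sources used here. A response to cLTP, which the design names, may also account for the fall and stays open.

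The fall of microglia and macrophage markers at 10 and 120 min (adjusted p = 0.25 and 0.38 with an estimated correlation) used the same 2 mock libraries, against which camera also put the list lower at 5 min (median -0.14, adjusted p = 0.003) and 60 min (-0.15, adjusted p = 0.00032). At 120 min the median against the 5 min libraries was -0.27, with 13 of 15 members below 0 (fry adjusted p = 0.032 over 3 times). Against the 60 min libraries the median was -0.19 and the list did not pass (fry adjusted p = 0.061 over all lists and neighbouring comparisons). Chance values of the shared mock libraries were thus argued against at 120 min only by the first of these comparisons. They cannot be told apart from a fall at 10 min, where 2 libraries per group gave -0.1 against 5 min (fry adjusted p = 0.2; -0.03 and adjusted p = 0.5 at 60 min). A lower share of microglial RNA may account for the fall at 120 min: all 15 members lay below 0, 11 of them past the threshold, and the SD of their log2 fold changes, 0.15, was small beside the median of -0.37. Regulation of the same genes within microglia by cLTP would give a like picture and was not tested.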

How the results depend on the processing

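The fit without the 5 min libraries and the fit with sample weights were chosen after the data were examined; all other alternatives were planned. Counts of genes higher at 60 and 120 min stayed within 1.5 times under RLE factors, library totals, limma-voom, filters (at least 1 CPM in 2 libraries left out 0 genes, a mean of at least 1 CPM left out 22), a pseudocount of 0.1 and sample weights. The number of genes higher at 10 min was 2 with RLE factors, 2 with library totals, 2 with limma-voom, 2 with only the 2 groups compared, 2 at 1.5-fold or more, 1 at an adjusted p under 0.01 and 9 without the 5 min libraries, where 3 genes were lower. An adjusted p under 0.01 gave 90 lower at 60 min, 1090 lower at 120 min, 390 from 10 to 60 min, 2574 from 60 to 120 min, 0 from 5 to 10 min, 2643 at any time and 32 lower at both 60 and 120 min. A minimum of 1.5-fold gave 222 higher and 23 lower at 60 min, 590 higher and 61 lower at 120 min, 0, 220 and 562 for the neighbouring times and 787 at any time; these follow from the stricter thresholds. Library totals gave 3123 lower at 120 min and 0 from 5 to 10 min, and moved the median of all genes to -0.067 at 120 min. The repeat numbers were not taken to pair the samples: deviations of same-numbered samples correlated between -0.16 and 0.27 over the 10 pairs of groups, with 3 pairs over 0.1 (those among mock, 5 and 10 min). With a replicate block 130 genes differed from 5 to 10 min, 1 was lower at 10 min, 521 were higher and 209 lower at 60 min, and 2341 higher and 1946 lower at 120 min. Of the gene lists, 4, 13, 9 and 16 passed camera at 5, 10, 60 and 120 min; with an estimated correlation 0, 0, 3 and 0 did, directional fry gave 0 at 5 min and 2 at 10 min, and mixed fry 0 and 7. Leaving out 1 library at a time, with a lone sample assumed to vary like the other groups, gave 0 to 110 genes higher and 0 to 588 lower at 5 min, 0 to 9 higher and 0 to 3 lower at 10 min, 341 to 600 higher and 89 to 289 lower at 60 min, 1106 to 2205 lower at 120 min, 0 to 740 from 5 to 10 min, 398 to 833 from 10 to 60 min, 2692 to 4577 from 60 to 120 min and 2489 to 5732 at any time. In the same refits small log2 differences that had not passed crossed 0: Fos (-0.44 to 0.04), Egr1 (-0.12 to 0.04) and Npas4 (-0.27 to 0.18) at 5 min, Bdnf (-0.14 to 0.01) and Nptx2 (-0.15 to 0.11) at 10 min, and Homer1 from 10 to 60 min (-0.07 to 0.11), the last also with library totals (-0.02). Beyond the fewer genes or libraries of a setting, the cause was not tested. Of 195 results of named genes past the threshold, none changed direction under the settings run; 193 kept their call with RLE factors, 184 with library totals, 192 with limma-voom, 193 with the block and 175 to 195 without each library. The stricter thresholds kept 174 of the 195 at an adjusted p under 0.01 and 124 at 1.5-fold or more. Leaving out a library could hardly turn the direction of these results. The largest rises and falls were named only where both libraries of 1 group lay on the same side of both of the other. List members were taken by p. Dropping a library outside the 2 groups compared leaves a log2 difference unchanged. DESeq2 was not run, since the table lists CPM and the written fallback was followed. Read-scale values were derived for limma-voom, so the data did not rule out a count model. A filter on a total above 0 removed no gene. Depth of 32961534 to 54040657 reads limits rare transcripts, and 2 libraries per group limit small changes. In the simulation of 120 min against mock, 14 of 50 genes were recovered at the smallest fold. Far fewer genes were changed there than the 4327 called at 120 min in the data, whose median absolute log2 fold change was 0.3. The adjusted threshold is stricter where fewer genes change, so this recovery does not measure the sensitivity of the 120 min comparison.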

Other observations

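The tests of zinc-finger families were chosen after the falls at 60 min were seen, and those of the span of genes that fell back or rose further and of genes lower at 120 min were not written down before their results. The test of zinc-finger genes against expression-matched sets and the other tests of span were written down before. Genes are not independent replicates in these tests.

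Genes of zinc-finger families, transcription factors that bind DNA through zinc-coordinated fingers, made up a large part of the falls at 60 min. Taken by symbols starting with Zfp, Zbtb, Zbed, Zic or Klf and a number, 50 of the 227 genes lower at 60 min belonged to them (22%), against 226 of all 11615 genes (1.9%), with an odds ratio of 17.98 (Fisher's exact test, adjusted p = 1.8e-38 over 5 sets). Within the 227, 38 of the 133 genes that rose between 60 and 120 min belonged to them (28.6%), against 12 of the other 94 (12.8%, odds ratio 2.72, Fisher's exact test, adjusted p = 0.0082 over 6 tests). The 60 min libraries that selected these genes also enter that rise. Genes higher at 60 min held 21 of 539 (odds ratio 2.15, adjusted p = 0.0037), and the sets lower and higher at 120 min had adjusted p of 0.13 and 0.099. Over the 226 genes the median log2 fold change was -0.12 at 60 min and 0 at 120 min, and the median change from 60 to 120 min was 0.13. Examples, chosen after their values were seen, are Zfp672 (-0.54 at 60 min, 0.48 at 120 min), Zbtb7b (-0.33 and 0.68), Zic2 (-0.57 and 0.33) and Zfp592 (-0.35 and 0.45).

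Low expression of zinc-finger genes does not account for this: 22.1% of them were lower at 60 min, against 0.9% to 4.4% in 10000 expression-matched random sets. A hypothesis is that transcripts with short lifetimes, which may include many of this family, drop during a brief pause in their synthesis and recover after it; RNA lifetimes were not measured here, and reads shared between related finger genes were not examined.

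Genes that rose by 60 min were short. Their median genomic span was 9.4 kb (533 genes with a usable span), against 22.1 kb for genes higher at 120 min and not at 60 min (1892 genes, permutation p = 1e-04, the smallest that 10000 permutations can give). Expression-matched random sets had medians from 19.8 to 25.6 kb. Within the genes higher at 60 min, those that fell back by 120 min had a median span of 6.4 kb (176 genes) and those that rose further 15.2 kb (215 genes, permutation p = 1e-04). Genes lower at 120 min were long, with a median of 33.6 kb against 21.4 to 24.4 kb in matched sets. A hypothesis is that the time needed to transcribe a gene may limit how early its mature RNA can rise. It does not address the genes that fell back or were lower at 120 min. Transcription rates were not measured here, and span alone cannot tell this hypothesis apart from other traits of short genes.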
